A study of Drosophila melanogaster with 8 samples.

How the data were processed

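RNA of 3 Drosophila melanogaster cell lines was hybridised to Affymetrix DrosGenome1 arrays, 3 arrays of RasV12 (passage 12), 4 of CL8 and 1 of L2. Per the series' design text, each sample came from its own T-flask at 70% confluence, RNA was extracted on RNeasy columns, and the authors computed expression values with GCRMA, a method that corrects probe intensities for background by their GC content, normalizes across arrays and summarises the probes of a probe set. The values are log2 expression values as deposited. The log2 unit was taken from GCRMA and from the range of the values, and whether all arrays passed through 1 GCRMA run is not given in the sources used here. The values of RasV12 have a median of 14 decimals and those of CL8 and L2 of 9. All columns of the value table were used, and the group of each was taken from its sample title.

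Of the probe sets, 44 controls were set aside and 13966 tested. Gene names came from the platform's annotation, updated through gene identifiers to the symbols of the RefSeq annotation of assembly Release 6 plus ISO1 MT, which was used for names only. Of the tested probe sets, 12443 had 1 gene, 327 several and 1196 none in that table, and 12394 of those with 1 gene matched a RefSeq gene (49 did not and kept the platform's symbol). These cover 10845 genes, 1209 of them with 2 or more probe sets. A gene was represented by its probe set with the highest mean over all arrays. Ras85D is paired with no probe set there and is not analysed here, so the transgene was not checked.

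Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), as the design text names limma. One fit of all 8 arrays on the deposited log2 values gave RasV12 against CL8, L2 against CL8 and RasV12 against L2, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. With 1 array, L2 adds nothing to the estimate of spread and is assumed to vary like the other lines. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.114, 0.167 and 0.172 in these comparisons. Because the arrays do not share one distribution, all fits were repeated after quantile normalization (rescaled), and a direction is given as such only where both scalings have it.

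Signal over background was judged by 23 control probe sets for transcripts that are neither of the fly nor spiked for hybridisation. Their highest value was 2.98 to 3.47 on the RasV12 and CL8 arrays and 4.04 on the L2 array. A line counted as within the controls unless most of its arrays were above that value. A fold against such a line is given as "at least", from the mean of the brighter line and, per array of the dimmer line, the higher of its own value and the highest control.

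The genes named were chosen by a rule fixed before the data were examined. It took the 10 genes (8 in comparisons with L2) with the largest difference in each direction, and 2 (1 with L2) whose symbol is a CG number, if called, without overlap between the arrays of both lines, and with a mean in the higher line above that line's median. It added up to 4 members per gene list with the largest difference between RasV12 and CL8, and any called member of lists with 5 or fewer calls. The text gives a part of the list members so chosen. Gene lists of pathways, complexes and cell type markers were fixed at the same time. Members were matched by symbol or an unambiguous synonym. Those without a match were left out, so a list can lack core genes. The cell cycle list lacked CycA, Cdk1, stg, polo and Myc among others, glycolysis Tpi, Pyk and Ldh, and the contractile list Mhc, Act57B and Tm1. In all, 34 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list of transposable elements matched 0 genes and was not tested.

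Arrays were clustered as the design text describes, on the top 20% of probe sets by standard deviation (2793), with 1 minus the Pearson correlation and average linkage. The class discrimination with pamr that it names was not repeated. Lists were also set against 10000 random lists of the same size and brightness, and gene families were tested with Fisher's exact test, two-sided, adjusted over the families and both directions.

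The scripts were tested on simulated data with 13966 probe sets, each with its real mean over all arrays and its real spread. At each size 50 probe sets were changed, the noise was independent and no other shift separated the lines. In RasV12 against CL8, limma recovered 84% of probe sets changed by 1 on the log2 scale, 96% of those changed by 2, and falsely called 9 unchanged ones. In L2 against CL8 it recovered 68% and 78% with 6 false calls, and in RasV12 against L2 42% and 88% with 8. The real comparisons called far more probe sets than were changed here, and their arrays do not share one distribution. These rates therefore check the scripts and do not carry over to the real calls. Over 680 tests of unchanged lists per comparison on 10845 genes, camera called 0, 1 and 0 in these tables, whose genes vary independently, and it called a list shifted by 1 in 20 of 20 simulated tables in each.

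The alternatives fixed before the data were examined were a filter on dim probe sets, median centring, quantile normalization, a floor at 4 on the log2 scale, eBayes with trend and robust, array weights, a fit without L2, the replicate number as a block, each RasV12 and CL8 array left out, 1 probe set per gene, the other list tests, and other settings of the clustering. Alternatives added after seeing the data were the removal of CL8 arrays 3 and 4 or 1 and 2, a filter on the background controls, and rescaling together with an estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.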

Results

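Gene expression was measured in 3 Drosophila cell lines on 8 Affymetrix DrosGenome1 arrays. RasV12 is a line derived from embryos that expressed an oncogenic form of Ras, a GTPase whose V12 form stays active and signals through the MAP kinase cascade. It was profiled at passage 12 on 3 arrays. The lines CL8 and L2 were profiled on 4 arrays and 1 array, and the labels describe L2 only as a cell line. The cells of every line were at 70% confluence, and each RNA came from its own T-flask. The p-values therefore measure the spread between flasks and arrays of one line and say nothing of how lines of one kind vary. L2 has no replicate, so each test with L2 assumes that it varies like the other lines.

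The arrays of one line were close to each other, and the lines did not share one distribution of values. The Pearson correlation over 13966 probe sets was 0.997 between RasV12 arrays and 0.992 to 0.998 between CL8 arrays. It was 0.933 to 0.941 between RasV12 and CL8, 0.946 to 0.952 between L2 and CL8, and 0.936 to 0.940 between RasV12 and L2. The 75th percentile of the log2 values was 8.14 ± 0.042 (SD, n = 3) in RasV12, 8.97 ± 0.010 (n = 4) in CL8 and 8.32 in L2. Each comparison is for this reason given on the deposited values and again after quantile normalization, called rescaled here. Rescaling moved the median difference of all probe sets by 0.13 between RasV12 and CL8, by -0.26 between L2 and CL8 and by 0.38 between RasV12 and L2. Probe sets above the highest background control numbered 9017 in RasV12, 9306 in CL8 and 8691 in L2.

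**Figure D1:**
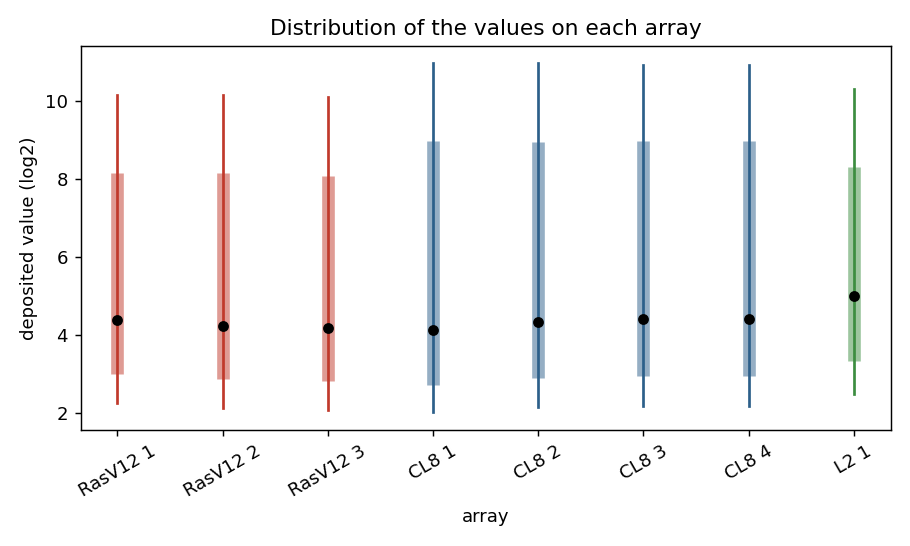
Distribution of the deposited log2 values of 13966 probe sets on each array, one column per array. The dot is the median, the thick bar spans the 25th to 75th percentile and the thin line the 10th to 90th. The 75th percentile averaged 8.14 in RasV12 and 8.97 in CL8.

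The first question was how the lines group by overall expression. The 4 CL8 arrays clustered with L2 before either joined RasV12. The deposited values split the same way, with a median of 14 decimals in RasV12 and 9 in CL8 and L2. A difference between the lines and a separate processing run of RasV12 therefore cannot be told apart in this grouping. Over the 2793 most variable probe sets, the mean distance (1 minus the Pearson correlation) was 0.279 ± 0.0089 (SD over 4 pairs of arrays) between L2 and CL8. It was 0.419 ± 0.018 (12 pairs) between RasV12 and CL8 and 0.394 ± 0.012 (3 pairs) between RasV12 and L2. Within lines it was 0.0119 ± 0.0019 (3 pairs) for RasV12 and 0.0272 ± 0.011 (6 pairs) for CL8. No test was made of these distances, since pairs of arrays are not independent. CL8 arrays 3 and 4 joined at 0.00717 and CL8 arrays 1 and 2 at 0.0206, and these pairs joined at 0.0339. The middle 18S ribosomal RNA control probe set read 15.33 and 14.53 on CL8 arrays 3 and 4 and 10.13 and 9.50 on CL8 arrays 1 and 2. The labels name no batch, so it stays open whether these pairs were labelled apart, and the tests treat the 4 CL8 arrays as independent.

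**Figure D2:**
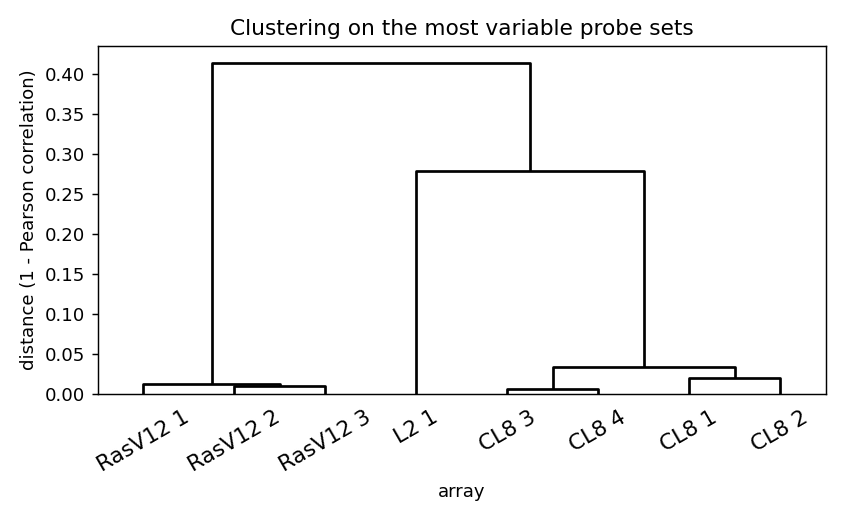
Average-linkage clustering of the 8 arrays on the 2793 most variable probe sets. The vertical axis is the distance, 1 minus the Pearson correlation. L2 joins the CL8 arrays at 0.279, and RasV12 joins both at 0.414. Whether RasV12 was processed in a separate run is not given.

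RasV12 was compared with CL8 to find which genes differ between these lines. Each is a single line, and a passage is given for RasV12 only. An effect of oncogenic Ras therefore cannot be told apart from other differences between the lines or from a separate processing run. Among the genes with the largest differences, GstE6, a glutathione S-transferase, read 13.71 ± 0.030 (SD, n = 3) in RasV12 and 3.07 ± 0.16 (n = 4) in CL8, a difference of at least 1430-fold. trol, which encodes the basement membrane proteoglycan perlecan, was at least 993-fold higher, at 13.18 ± 0.16 against 2.80 ± 0.12. Towards CL8, DptB, a diptericin, was at least 142-fold lower in RasV12, and unpg, a homeobox gene, at least 483-fold lower.

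The rule for large differences took 12 genes towards RasV12. tok, a tolloid-type metalloprotease, was higher by 9.48 on the log2 scale (9.86 rescaled; limma adjusted p = 2.76e-08). Jhbp1 was higher by 9.48 (9.80 rescaled) and Sox102F, a SOX transcription factor gene, by 7.92 (8.24 rescaled). The other genes of this group lay within the background controls in CL8, so that only a bound can be given. eIF4E3, a cap-binding protein gene, was at least 296-fold higher and the carbonic anhydrase gene CAH2 at least 247-fold higher. The cytochrome P450 genes Cyp6a17 and Cyp9c1 were at least 215-fold and 200-fold higher. pain, which encodes a TRP channel, was at least 117-fold higher, CG9593 at least 174-fold and CG9338 at least 97.8-fold.

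Towards CL8 the rule likewise took 12 genes. Sp1, a zinc finger transcription factor gene, was at least 449-fold lower in RasV12, Cyp6w1 at least 441-fold, CG3246 at least 1050-fold and CG11585 at least 112-fold. Mec2 was lower with a log2 difference of -8.83 (-8.39 rescaled). GlcAT-P, a glucuronyltransferase gene, differed by -8.61 (-8.16 rescaled) and GILT3 by -7.36 (-6.78 rescaled). Ntan1 differed by -7.07 (-6.46 rescaled) and Idgf3, an imaginal disc growth factor gene, by -6.77 (-6.13 rescaled). tkv, which encodes a type I BMP receptor, differed by -8.46 (-8.02 rescaled; limma adjusted p = 4.4e-09) on its brighter probe set. Its second probe set was called the other way, at 3.68 (4.2 rescaled), so no direction holds for the gene as a whole.

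**Figure D3:**
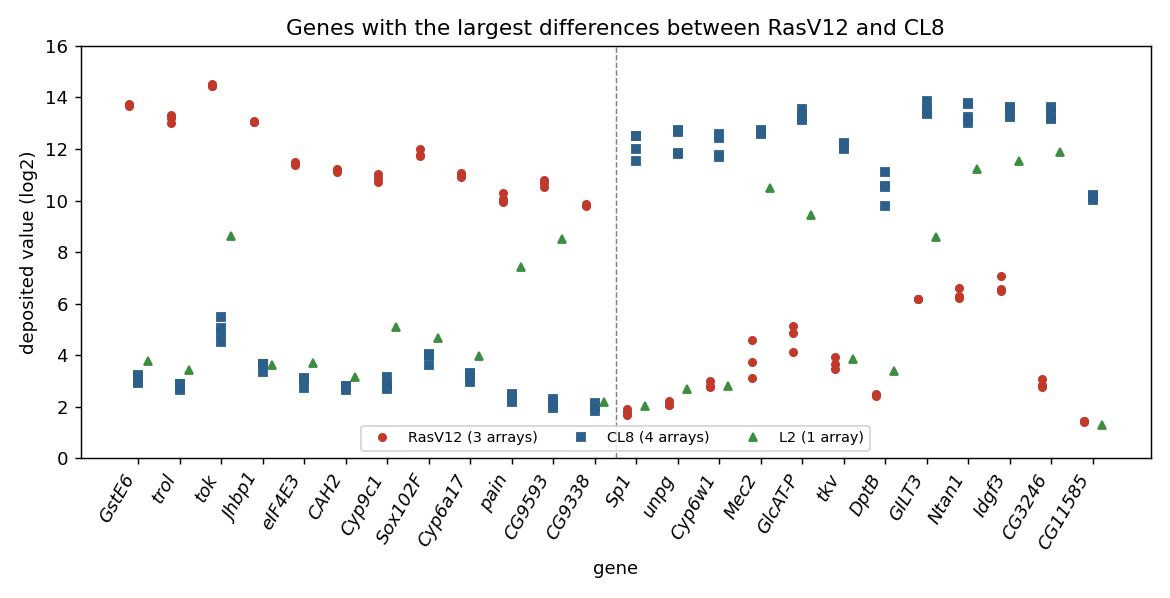
Deposited log2 values of the 24 genes that the rule for named genes took for large differences between RasV12 and CL8, one point per array. Circles are RasV12, squares CL8 and triangles L2. The 12 genes left of the dashed line are higher in RasV12 and the 12 to its right lower. L2 reads 8.63 for tok and 11.90 for CG3246.

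The list of targets and feedback genes of Ras signalling was split, and pnt, rho, vn and Ilp6 on it matched no measured gene. Of 12 such genes measured, 4 were higher in RasV12, 4 lower and 4 did not pass the test, with the same counts adjusted over the list alone (6 higher and 4 lower rescaled). Mkp3, a phosphatase that acts on MAP kinase, read 10.21 ± 0.13 in RasV12 and 5.51 ± 0.73 in CL8, a log2 difference of 4.71 (5.21 rescaled; limma adjusted p = 1.23e-05). kek1, a feedback inhibitor of the EGF receptor, was higher by 2.87 (3.60 rescaled), and aos, a secreted antagonist of that receptor, by 1.83 (2.46 rescaled). These sizes depend on the CL8 arrays, with kek1 at 3.51 without CL8 arrays 3 and 4 and 2.23 without 1 and 2, and aos at 2.54 and 1.13 (removals chosen after seeing the data, here and below). On the L2 array Mkp3 read 10.9 and aos 8.54, near their RasV12 means of 10.21 and 8.41. These 2 genes therefore do not set RasV12 apart from L2, while kek1 read 7.75 in L2, near its CL8 mean of 7.42. puc, a phosphatase of the JNK pathway and the only lower gene of this list named here, differed by -2.22 (-1.42 rescaled). In the list of the EGFR, Ras and MAP kinase pathway itself, Ras85D, phl, rl, Gap1, vn and rho matched no measured gene. Of its 12 measured genes, 3 were higher and 5 lower (7 lower adjusted over the list alone). Rescaled, 6 were higher and 3 lower. Egfr differed by -2.27 (-1.81 rescaled) and Sos, the exchange factor that loads Ras with GTP, by -2.19 (-1.68 rescaled). Neither list was called by camera (adjusted p = 0.274 and 0.893, and 0.679 and 0.602 rescaled). Ras85D, the gene behind the transgene, is not analysed here because no probe set is paired with it in the names used.

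Mesoderm and muscle genes differed in both directions, and more of them were called higher when rescaled. twi, the transcription factor that specifies mesoderm, read 9.34 ± 0.24 in RasV12 and 2.82 ± 0.25 in CL8, at least 69.4-fold higher. htl, an FGF receptor of the mesoderm, was higher by 6.15 (6.57 rescaled), and kirre, a myoblast fusion receptor, was at least 25-fold higher. rst, which the rule took from the same list, went the other way and was at least 6.5-fold lower. Of 24 genes of mesoderm and muscle precursors, 6 were higher, 3 lower and 15 did not pass, with the same counts adjusted over the list alone (10 higher and 6 lower rescaled). Only 17 of them lay above the background controls in RasV12 or CL8, of which 6 were higher and 2 lower in both scalings. Camera compares a list with the other genes, and this list had a median log2 difference of 0.0046 and a mean of 0.69. The list was called higher by camera (adjusted p = 0.0272) on deposited values only (adjusted p = 0.452 rescaled), and adjusted p = 0.675 with an estimated correlation. It was not called without CL8 arrays 1 and 2 (adjusted p = 0.0742). Of 23 contractile genes, 4 were higher and 4 lower, over the list alone as well (12 higher and 3 lower rescaled). Only 15 of them lay above the background controls in RasV12 or CL8, of which 4 were higher and 0 lower in both scalings. bt, which encodes the muscle kinase projectin, was higher by 4.01 (4.39 rescaled) on the probe set used while its other one did not pass (0.42, and 0.54 rescaled), the myosin light chain gene Mlc2 by 3.00 (3.32 rescaled) and Msp300 at least 3.14-fold on the brightest of its 3 probe sets, the others lying within the background controls. The actinin gene Actn was called lower only on the deposited values, at -0.90 against -0.08 rescaled. The contractile list had camera adjusted p = 0.0161, adjusted p = 0.0569 rescaled and adjusted p = 0.675 with an estimated correlation.

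Matrix and junction genes were higher in RasV12 more often than lower. Of 22 basement membrane and integrin genes, 11 were higher and 8 lower, with the same counts adjusted over the list alone (11 and 6 rescaled). Ndg, which encodes nidogen, was at least 118-fold higher. Tig, an integrin ligand gene, was higher by 7.28 (7.60 rescaled) and Ppn, which encodes papilin, by 5.57 (5.99 rescaled). For this list camera gave adjusted p = 0.0083, adjusted p = 0.0678 rescaled and adjusted p = 0.208 with an estimated correlation. Of 23 genes of epithelial polarity and junctions, 11 were higher and 7 lower, over the list alone as well (16 and 4 rescaled). The septate junction gene Lac was higher by 4.51 (5.23 rescaled; 5.24 without CL8 arrays 3 and 4, 3.78 without 1 and 2) and Gli, which encodes gliotactin, by 2.41 (3.17 rescaled). The apical determinant crb was lower, with a difference of -2.64 (-1.88 rescaled), as was the adhesion gene ed at -1.68 (-0.83 rescaled). This list was called higher in both scalings (camera adjusted p = 0.0199 and 0.0241 rescaled), and had adjusted p = 0.225 with an estimated correlation.

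Most genes of both mitochondrial lists were lower in RasV12. All 64 mitochondrial ribosomal protein genes measured were lower in RasV12, over the list alone as well, and 56 of them were lower in both scalings. The median log2 difference was -1.83 (-1.0 rescaled). mRpS9 read 5.14 ± 0.27 in RasV12 and 10.54 ± 0.35 in CL8, a difference of -5.40 (-4.83 rescaled), and mRpL50 differed by -3.79 (-3.0 rescaled). Camera gave the list adjusted p = 2.12e-15 (8.13e-14 rescaled), and adjusted p = 0.208 with an estimated correlation. Of 21 oxidative phosphorylation genes, 20 were lower and 1 higher, over the list alone as well (16 and 2 rescaled). ox, a subunit of respiratory complex III, differed by -2.42 (-1.78 rescaled) and SdhC, of succinate dehydrogenase, by -2.20 (-1.37 rescaled). Camera called this list too (adjusted p = 6.01e-05, and 0.00535 rescaled), with adjusted p = 0.280 at an estimated correlation. Glycolysis genes went the other way, with 5 of 10 higher and 1 lower, over the list alone as well (8 and 0 rescaled). Pfk, the phosphofructokinase gene, was higher by 1.63 (2.42 rescaled), Eno by 0.63 (1.37 rescaled) and Hex-A by 0.58 (1.41 rescaled), while Mdh1 differed by -0.82 as deposited and by -0.08 rescaled. Glycolysis was called at camera adjusted p = 0.024 (0.00535 rescaled), but not without CL8 arrays 3 and 4 (adjusted p = 0.153), and had adjusted p = 0.675 with an estimated correlation.

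The lists of DNA replication, cell cycle, proteasome and cytoplasmic ribosomal protein genes were called lower as deposited. Most of these calls were lost on rescaling, and none held with an estimated correlation. Of 29 DNA replication genes, 24 were lower and 1 higher (25 and 1 over the list alone; 15 and 5 rescaled), and 15 were lower in both scalings. Orc2, of the origin recognition complex, differed by -3.95 (-3.55 rescaled) and the GINS gene Psf2 by -3.05 (-2.43 rescaled). The list had camera adjusted p = 0.00021, adjusted p = 0.0569 rescaled and adjusted p = 0.208 with an estimated correlation. Of 26 cell cycle genes, 22 were lower and 1 higher, over the list alone as well (12 and 4 rescaled), and 12 were lower in both scalings. Rbf2 differed by -3.33 (-2.86 rescaled) and the mitotic cyclin gene CycB by -2.28 (-1.46 rescaled), with camera adjusted p = 0.00149 (0.153 rescaled) and adjusted p = 0.208 with an estimated correlation. Of 39 proteasome genes, 27 were lower and 4 higher (28 and 4 over the list alone; 23 and 6 rescaled), among them Rpn12 at -1.75 (-0.93 rescaled). This list was called in both scalings (camera adjusted p = 0.00567 and 0.0241 rescaled), and had adjusted p = 0.600 with an estimated correlation. Of 37 cytoplasmic ribosomal protein genes, 28 were lower and 1 higher as deposited (28 and 3 over the list alone), but 11 were higher and 8 lower when rescaled, among these RpS18 at -1.12 (-0.51 rescaled). Its call (camera adjusted p = 0.0199) was lost on rescaling (adjusted p = 0.816), without CL8 arrays 3 and 4 or 1 and 2 (adjusted p = 0.0979 and 0.0516) and with an estimated correlation (adjusted p = 0.675). The reference gene RpL32 differed by -0.51 as deposited and by 0.08 rescaled, where it did not pass the test.

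**Figure D4:**
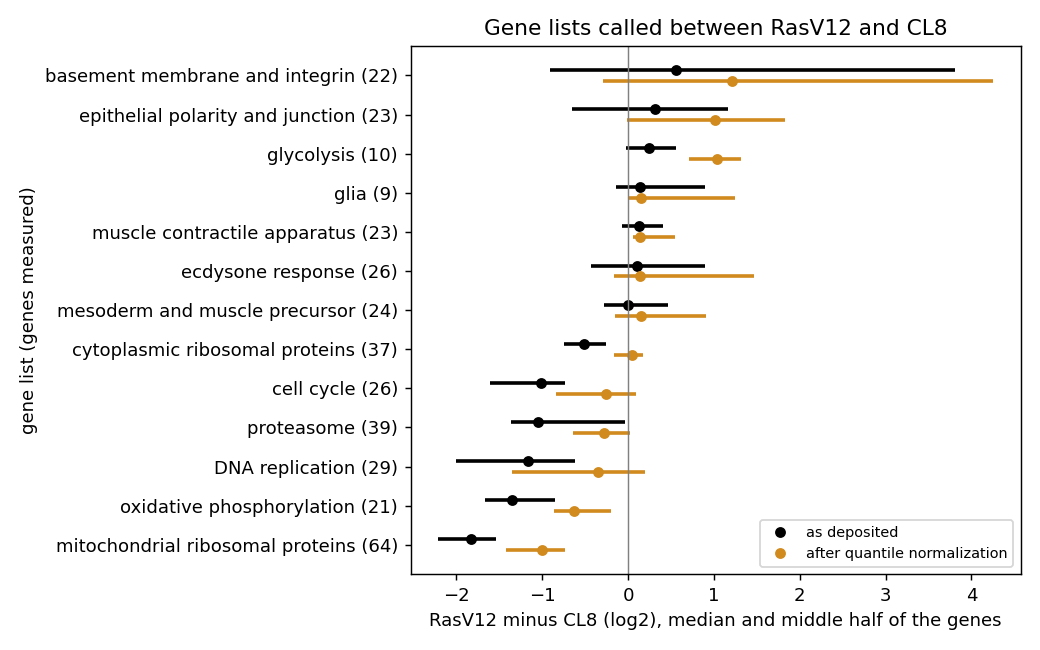
Gene lists called by camera between RasV12 and CL8, with the number of genes measured. Dots are medians of the log2 difference and bars span the 25th to 75th percentile of the genes, as deposited in black and after quantile normalization in orange. The median of the mitochondrial ribosomal proteins is -1.83 as deposited and -1.0 rescaled.

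Camera did not call the blood cell, Hox and sex determination lists, in which single genes differed in both directions. Of 25 hemocyte genes, 8 were higher and 11 lower (12 lower over the list alone; 10 and 11 rescaled), with camera adjusted p = 0.874 (0.782 rescaled). Pxn, which encodes peroxidasin, differed by -6.45 (-5.94 rescaled; -7.43 without CL8 arrays 3 and 4, -5.47 without 1 and 2) and eater, a phagocytic receptor gene, by -5.87 (-5.24 rescaled). ush, a cofactor of GATA factors, differed by -4.27 (-3.60 rescaled) and Pvr, a PDGF and VEGF receptor, by -3.33 (-2.63 rescaled). Of 26 wing disc patterning genes, 17 were lower and 2 higher, over the list alone as well (14 and 3 rescaled). ptc, the Hedgehog receptor, was at least 56.6-fold lower, salr differed by -1.79 (-1.61 rescaled) and kni by -1.28 (-1.07 rescaled), while tsh was at least 19.6-fold higher. The wing disc list was called only when rescaled (camera adjusted p = 0.216 and 0.0166 rescaled), and with an estimated correlation had adjusted p = 0.767 (0.327 rescaled). Of 8 Hox genes and cofactors, 5 were lower and 1 higher, over the list alone as well, with camera adjusted p = 0.274 (0.082 rescaled). Antp differed by -6.56 (-6.03 rescaled), and on the probe sets used cad and ftz were at least 4.24-fold and 2.60-fold lower. Of 13 genes of dosage compensation and sex determination, 9 were lower and 2 higher, over the list alone as well (6 and 5 rescaled), with camera adjusted p = 0.216 (0.679 rescaled). Sxl, the switch gene of female development, was higher by 3.57 (4.21 rescaled). msl-2 differed by -3.23 (-2.62 rescaled), msl-3 by -3.79 (-3.20 rescaled) and the acetyltransferase gene mof by -1.82 (-1.0 rescaled). The sex of the lines and any effect of Sxl on these genes were not tested.

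Single genes stood out in further lists that camera did not call or called weakly. Of 30 genes of oxidative stress and xenobiotic response, 7 were higher and 12 lower, over the list alone as well (10 and 11 rescaled), and camera did not call the list (adjusted p = 0.455, and 0.939 rescaled). Of 9 tracheal genes, 1 was higher and 4 lower (1 and 5 rescaled), and of 14 germline genes 2 were higher and 5 lower (4 and 7 rescaled), over the lists alone as well. The higher ones as deposited were the tracheal FGF receptor gene btl, which was at least 69.8-fold higher, and the germline genes orb and tud, higher by 6.18 (6.56 rescaled) and 3.43 (4.22 rescaled). In the Dpp list (6 of 14 higher and 5 lower; 8 and 4 rescaled), tld was higher by 4.37 (4.74 rescaled) and Mad by 1.95 (2.72 rescaled), while Dad differed by -1.58 (-0.94 rescaled). In the Hedgehog list (2 of 14 higher and 8 lower; 3 and 5 rescaled), boi was higher by 2.16 (2.63 rescaled; 1.44 without CL8 arrays 3 and 4, 2.88 without 1 and 2), while cos and Su(fu) differed by -2.34 (-1.88 rescaled) and -1.44 (-0.66 rescaled). In the Notch list (6 of 18 higher and 6 lower; 10 and 4 rescaled), E(spl)m6-BFM and fng were higher by 2.51 (2.81 rescaled) and 1.92 (2.72 rescaled). In the JAK-STAT list (2 of 10 higher and 1 lower; 5 and 2 rescaled), chinmo was higher by 3.55 (4.27 rescaled) and Stat92E lower, at -1.91 (-1.18 rescaled). In the Hippo list (3 of 14 higher and 10 lower, or 11 lower over the list alone; 8 and 4 rescaled), kibra was higher by 1.63 (2.29 rescaled) and wts lower, at -1.96 (-1.64 rescaled). Camera called none of these 7 lists (smallest adjusted p = 0.157 for Notch, and 0.383 rescaled for Hedgehog). Of 26 ecdysone response genes, 8 were higher and 7 lower, over the list alone as well (12 and 7 rescaled), with camera adjusted p = 0.0477, adjusted p = 0.227 rescaled and adjusted p = 0.675 with an estimated correlation. EcR, the ecdysone receptor gene, was higher by 2.51 (2.91 rescaled), Hsp27 by 2.11 (2.89 rescaled; 2.71 without CL8 arrays 3 and 4, 1.51 without 1 and 2) and Cyp18a1, an ecdysone-inactivating enzyme gene, at least 10.1-fold, while Cth differed by -3.36 (-2.57 rescaled). The ecdysone call was lost without RasV12 array 2 (adjusted p = 0.0538) or CL8 array 1 (adjusted p = 0.0555). Of 9 glial genes, 4 were higher and 1 lower, over the list alone as well (6 and 1 rescaled), with camera adjusted p = 0.0434, 0.203 rescaled, 0.0555 without CL8 array 1, 0.0503 without CL8 arrays 3 and 4, 0.069 without 1 and 2, and adjusted p = 0.675 with an estimated correlation.

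In all, limma called 6969 of 13966 probe sets between RasV12 and CL8 at the adjusted p threshold of 0.05, 1580 higher and 5389 lower. Of these calls 22.7% were higher, against 54.4% of the 9108 calls made when rescaled (4953 higher and 4155 lower). In both scalings, 1573 probe sets were called higher and 3574 lower, while 222 were called in opposite directions. At least 2-fold apart were 3778 of the calls (699 higher and 3079 lower), against 2544 when rescaled (1147 higher and 1397 lower), so the excess of lower calls of this size depends on the scaling. In both scalings 698 were so higher and 1386 lower, where the deposited values limit the higher side. Camera called 13 of 34 gene lists (7 higher and 6 lower relative to the other genes), 6 when rescaled and 5 in both. At the same correlation, 33 of 34 other splits of these 7 arrays into 3 and 4 also called lists (median 5.5). Mixed groups keep a part of the difference between the lines, so that count does not measure chance. A call at the preset correlation is weak evidence because none held with an estimated correlation. With an estimated correlation camera called 0 lists in either scaling, where the smallest adjusted p was 0.208 and 6 lists had an unadjusted p under 0.05 (5 rescaled), while fry called 27. For 631 of the called probe sets both lines lay within the background controls, where a call says little about a transcript.

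L2 was compared with CL8 in the same way. Argk1, which encodes arginine kinase, read 13.86 in L2 and 5.23 ± 0.42 (SD, n = 4) in CL8, a log2 difference of 8.63 (8.60 rescaled; limma adjusted p = 1.49e-06). rn, a zinc finger gene of limb development, was at least 232-fold higher and CG6836 at least 512-fold. PPO1, the prophenoloxidase of crystal cells, was higher by 6.97 (7.16 rescaled) and Ppn by 7.35 (7.49 rescaled). Among the genes lower in L2, Sp1, unpg and Cyp6w1 were at least 276-fold, 297-fold and 271-fold lower.

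Other genes at the top of this comparison were Nplp2, higher in L2 by 7.35 (7.52 rescaled), Cyp6a23 by 6.94 (7.14 rescaled) and Msr-110 by 6.55 (6.77 rescaled). For Nplp2, CL8 array 2 read 6.31 against 3.36 to 4.01 on the other CL8 arrays, and without it the difference was 8.02 (6.47 without CL8 arrays 3 and 4, 8.23 without 1 and 2). ATP8B, a phospholipid flippase gene, was at least 97.0-fold higher. The lower genes included DptB, at least 87.0-fold, CG11585, at least 68.8-fold, and Rbp4, at least 18.5-fold. GstS1 differed by -7.01 (-6.57 rescaled) and Ama by -6.17 (-5.74 rescaled). tkv was at least 275-fold lower on its brighter probe set, and its second probe set was again called the other way at 2.01 (2.29 rescaled).

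Some genes named for RasV12 against CL8 were looked up between L2 and CL8. They are a selection, both comparisons share the CL8 arrays, and no test of a common direction was made. Mkp3 was higher in L2 by 5.39 (5.74 rescaled), aos by 1.95 (2.43 rescaled), htl by 5.05 (5.35 rescaled) and Tig by 6.38 (6.59 rescaled). twi was at least 14.9-fold higher. ptc was at least 34.8-fold lower, and fng differed by -4.64 (-4.80 rescaled), opposite to its direction in RasV12. Antp differed by -5.16 (-5.0 rescaled) on its brighter probe set, the other lying within the background controls in both lines. Of 25 hemocyte genes, 13 were higher in L2 and 3 lower, over the list alone as well (10 and 3 rescaled), and camera did not call the list (adjusted p = 0.108, and 0.0545 rescaled). Unlike PPO1, which was higher, eater differed by -4.24 (-3.69 rescaled) and ush by -1.50 (-0.82 rescaled). Pxn did not pass the test between L2 and CL8, with a difference of 1.37 (1.89 rescaled). It passed without CL8 arrays 1 and 2 (2.35, adjusted p = 1.8e-05) and not without 3 and 4 (0.39, adjusted p = 0.0902), so no direction is claimed. On arrays 1 and 2 it read 11.75 and 12.02 against 9.86 and 10.01 on CL8 arrays 3 and 4.

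The mitochondrial ribosomal protein and DNA replication lists were called lower in L2 in both scalings at the preset correlation, though most of their genes did not pass when rescaled. Of 64 mitochondrial ribosomal protein genes, 57 were lower (60 over the list alone), and 21 were lower and 2 higher when rescaled. mRpL50 differed by -2.53 (-1.88 rescaled), and mRpS9 by -1.45 as deposited and by -0.78 rescaled, where it did not pass. The list had camera adjusted p = 3.7e-16 (0.000233 rescaled), and adjusted p = 0.197 with an estimated correlation. Of 29 DNA replication genes, 24 were lower (25 over the list alone) and 13 rescaled, with camera adjusted p = 5.05e-09 (0.000886 rescaled) and adjusted p = 0.184 with an estimated correlation. Psf2 was at least 24.0-fold lower, and Orc2 differed by -0.83 as deposited and by -0.45 rescaled, where it did not pass. The lists of oxidative phosphorylation (12 of 21 lower and 1 higher, 3 and 4 rescaled; adjusted p = 0.0036), cell cycle (16 of 26 lower and 3 higher, 7 and 6 rescaled; adjusted p = 0.0036), proteasome (23 of 39 lower and 7 higher, 12 and 7 rescaled; adjusted p = 0.0214) and neuronal genes (13 of 19 higher and 1 lower, 4 and 1 rescaled; adjusted p = 0.0351) were called as deposited only. Of the 13 neuronal genes, 7 were above the background controls in L2 or CL8. Adjusted over the list alone the first counts were 12, 16, 23 and 14. The proteasome call was also lost without CL8 arrays 3 and 4 or 1 and 2 (adjusted p = 0.0581 and 0.053). With an estimated correlation these 4 lists had adjusted p = 0.607, 0.201, 0.616 and 0.762, and at the preset correlation rescaled adjusted p = 0.955, 0.811, 0.717 and 0.266.

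Limma called 8636 probe sets between L2 and CL8, 5345 higher and 3291 lower, on the assumption that L2 varies like the other lines. Rescaled, 5245 were called, 2819 higher and 2426 lower, so that the share of higher calls went from 61.9% to 53.7%. At least 2-fold apart were 1265 higher and 1934 lower as deposited, 984 and 1001 rescaled, and 702 and 914 in both scalings. Of the calls on deposited values, 2658 were of probe sets within the background controls in both lines. Camera called 6 of 34 lists, 2 of them in both scalings. With an estimated correlation camera called 0 lists in either scaling, where the smallest adjusted p was 0.184 and 3 lists had an unadjusted p under 0.05 (2 rescaled), while fry called 24.

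RasV12 was compared with L2 for the same question as with CL8. GstE6, trol and Jhbp1 were again far higher in RasV12, at least 813-fold, 565-fold and 518-fold. ogre, a gap junction innexin gene, read 11.95 ± 0.14 (SD, n = 3) in RasV12 and 3.35 in L2, at least 240-fold higher, and Nrt, the cell adhesion gene neurotactin, was higher by 8.49 (9.38 rescaled; limma adjusted p = 0.000372). Single blood cell genes were higher in L2, among them Pxn at -7.81 (-7.84 rescaled), PPO1 at -7.67 (-7.81 rescaled) and the scavenger receptor gene Sr-CIV at -6.86 (-7.04 rescaled). Of 25 hemocyte genes, 15 were lower in RasV12 and 3 higher, over the list alone as well (13 and 4 rescaled), and camera did not call the list (adjusted p = 0.292, and 0.177 rescaled). CG6836 was at least 474-fold lower in RasV12, Nplp2 at least 313-fold and rn at least 199-fold.

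Other genes at the top were eIF4E3, CAH2, Mnr and CG3397, at least 169-fold, 140-fold, 64.0-fold and 121-fold higher in RasV12. Msr-110 was at least 112-fold lower, while Ugt37D1 differed by -6.74 (-6.81 rescaled) and Mec2 by -6.66 (-6.82 rescaled). twi was higher in RasV12 than in L2 by 2.22 (2.50 rescaled), htl by 1.10 (1.22 rescaled), and kirre at least 14.2-fold. Of the Ras target genes, Mkp3 differed by -0.68 (-0.53 rescaled) and aos by -0.12 (0.03 rescaled), while kek1 was higher by 2.53 (2.76 rescaled). The median of the 12 genes of that list was -0.096 (0.092 rescaled). msl-2 differed by -3.60 (-3.67 rescaled). On its brighter probe set Sxl was higher by 3.76 (4.21 rescaled), while its second probe set differed by 0.69 and did not pass.

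Junction, glycolysis, Dpp and mitochondrial ribosomal protein lists were called in both scalings. Of 23 junction genes, 10 were higher in RasV12 and 3 lower, over the list alone as well (12 and 2 rescaled), with Gli higher by 5.34 (5.98 rescaled) and Lac by 4.49 (4.54 rescaled). For the junction list camera gave adjusted p = 1.14e-06 (0.00396 rescaled), and adjusted p = 0.0777 with an estimated correlation. Of 10 glycolysis genes, 6 were higher and none lower, over the list alone as well (7 rescaled), with Pfk higher by 2.57 (2.67 rescaled) and Eno by 0.90 (1.14 rescaled). For glycolysis camera gave adjusted p = 3.14e-05 (0.0114 rescaled), and adjusted p = 0.364 with an estimated correlation. Of 14 Dpp pathway genes, 9 were higher and 3 lower, over the list alone as well (11 and 2 rescaled), with tld higher by 3.93 (4.96 rescaled) and Mad by 2.10 (2.31 rescaled). For the Dpp list camera gave adjusted p = 0.000174 (0.0174 rescaled), and adjusted p = 0.364 with an estimated correlation. Of 64 mitochondrial ribosomal protein genes, 47 were lower and 2 higher (49 and 2 over the list alone; 37 and 3 rescaled), with mRpS9 at -3.95 (-4.05 rescaled). The list had camera adjusted p = 0.0136 (0.000181 rescaled), 0.0534 without RasV12 array 1, and adjusted p = 0.862 with an estimated correlation. The DNA replication list (9 of 29 higher and 7 lower, over the list alone as well; 10 and 6 rescaled) was placed higher by camera (adjusted p = 0.0136) at a median of 0.086 and a mean of -0.013, with adjusted p = 0.307 rescaled and 0.451 with an estimated correlation. The basement membrane list had a median of -0.31 and a mean of 0.77, and camera placed it higher (adjusted p = 0.049), with adjusted p = 0.455 rescaled and 0.364 with an estimated correlation. That call was also lost without RasV12 array 2 or 3 (adjusted p = 0.0625 and 0.0629) and without CL8 array 2, 3 or 4 (adjusted p = 0.055, 0.0602 and 0.0606), and without CL8 arrays 3 and 4 or 1 and 2 (adjusted p = 0.111 and 0.0984). The wing disc and oxidative phosphorylation lists were called only when rescaled (adjusted p = 0.0159 and 0.0176), and with an estimated correlation had rescaled adjusted p = 0.501 and 0.632.

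Limma called 7493 probe sets between RasV12 and L2, 1337 higher and 6156 lower, again assuming that L2 varies like the other lines. Rescaled, 6702 were called, 3077 higher and 3625 lower, so that the share of higher calls went from 17.8% to 45.9%. At least 2-fold apart were 839 higher and 2390 lower as deposited, 1204 and 1301 rescaled, and 836 and 1301 in both scalings. Of the calls on deposited values, 1955 were of probe sets within the background controls in both lines. Camera called 6 of 34 lists, 6 when rescaled and 4 in both. With an estimated correlation camera called 0 lists in either scaling, where the smallest adjusted p was 0.0777 and 4 lists had an unadjusted p under 0.05 (2 rescaled), while fry called 20.

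RNA quality was read from control probe sets for the 3' and 5' ends of 3 fly transcripts. The 3' minus 5' difference for eIF-4a was 1.14 ± 0.091 (SD, n = 3) in RasV12, 1.86 ± 0.25 (n = 4) in CL8 and 1.65 in L2. For actin it was 0.75 ± 0.12, 0.91 ± 0.50 and 0.82, and for GAPDH 1.33 ± 0.055, 1.36 ± 0.19 and 1.03. Averaged over these transcripts it was 1.07 ± 0.083 in RasV12 and 1.38 ± 0.24 in CL8 (two-sided exact permutation p = 0.0571).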

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

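In this part the calls by limma, the camera tests and the counts of other splits were fixed before the data were examined. All other tests were chosen after the results were seen. The first pattern is the excess of calls lower in RasV12 than in CL8 (5389 against 1580). More degraded RNA in RasV12 would give a larger 3' minus 5' difference there. Averaged over 3 transcripts this difference was not larger in RasV12 (RasV12 minus CL8 = -0.306, standard error 0.127). Most of that gap came from eIF-4a (1.14 in RasV12 against 1.86 in CL8), while GAPDH was close (1.33 against 1.36). The values show no sign of more degradation in RasV12 but cannot exclude it, since the deposited scale, itself in question, enters them. Separate normalization runs and a difference between the lines cannot be told apart, since the 75th percentile gap between RasV12 and CL8 (-0.839, SD within a line at most 0.042) restates the pattern, and L2, whose values have as many decimals as those of CL8, also differed from CL8 by -0.657. The RasV12 minus CL8 difference of spiked hybridisation controls averaged -0.213, which lay 0.619 ± 0.551 (SD over 4 transcripts) above that of fly probe sets of the same brightness, but 4 transcripts cannot give an exact p below 0.125, so a scale difference of whole arrays and a true excess of lower transcripts cannot be told apart. The biological explanation, that the lines differ in total mRNA or in many genes, stays open and was not tested.

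The second pattern is the lower level of all 64 mitochondrial ribosomal protein genes in RasV12 than in CL8. A scale difference that acts alike on all genes of one brightness may account for part of it, and the list lay below random lists so matched. The median of -1.83 lay -0.873 away from that of random lists of the same size and brightness (median -0.955, SD 0.134), and 0 of 10000 such lists were as low. The same setting gave random medians of -0.894 for glycolysis and -0.832 for junction genes, whose own medians were 0.25 and 0.31. For oxidative phosphorylation and the proteasome they were -0.873 and -0.527, against own medians of -1.35 and -1.05. There 29 and 9 of 10000 random lists were as low, so every list tried lay apart from its random lists. Their genes are drawn independently, so these counts cannot tell how rare such a distance is among genes that vary together. All 64 genes were called lower and 56 in both scalings, so these genes differed on the arrays, while the list call against other genes went from adjusted p = 2.12e-15 to 0.208 at the same median with a correlation estimated at 0.111, which random lists do not carry, and a biological cause was not tested.

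Other splits of the arrays did not reach the counts of probe sets, but 1 reached the count of lists. Of the 35 splits of the 7 RasV12 and CL8 arrays into 3 and 4, only 1, the real one, called 6969 probe sets or 3778 at least 2-fold apart, and the highest other split called 1 in both counts. The 13 lists called by camera were matched by another split, which put RasV12 arrays 2 and 3 with CL8 array 4 and also called 13, so 2 of 35 splits gave as many. Of the 34 other splits, 33 called at least 1 list (median 5.5) while none called more than 1 probe set. Mixed groups keep a part of the difference between the lines and add it to the spread within groups, so neither count measures chance. A list call at the preset correlation is weak evidence on these arrays, since none held with an estimated correlation.

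Among the 4 CL8 arrays, 19 of 121 values tested had 1 array far from the rest, where chance gives about 6.05, and genes that vary together are not independent. CL8 array 1 was the low one for kirre (2.19), Msp300 (3.06), ftz (4.39), Ndg (2.50), orb (3.11), Cyp18a1 (3.00), Jhbp1 (3.33), Sox102F (3.63), rn (2.74), PPO1 (4.19) and Cyp6a23 (3.19). That array also had the lowest 10th percentile of the CL8 arrays (2.00 against 2.14 to 2.18). Its highest background control was the lowest as well (2.98 against 3.22 to 3.41). Most of these genes read near that level, so a shift of all dim values on the array and outliers of single genes cannot be told apart. CL8 array 2 was high for twi (3.20), GstE7 (3.71), Ppn (5.06) and msl-3 (9.30), and low for Hex-A (8.92), Sxl (5.31) and Mnr (5.83). CL8 array 4 was high for Argk1 (5.85). In data outside the comparisons, the middle 18S ribosomal RNA control probe set reached 15.33 on CL8 array 3 and was 5.88 on the L2 array.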

How the results depend on the processing

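The genes followed here are the top genes of each comparison and others named in the text. Most were chosen for large differences, so few could lose a call. Of 2602 values of these genes under alternatives, 2595 kept direction and side of the threshold and 4 lost the call. Another 2 gained it (Pxn between L2 and CL8, without CL8 arrays 1 and 2 and with array weights). The last 1 turned, RpL32 between RasV12 and CL8, at 0.078 after quantile normalization. Over all probe sets of RasV12 against CL8, quantile normalization turned 222 calls and took the higher calls from 1580 to 4953. The cytoplasmic ribosomal protein list turned to a median of 0.048 under quantile normalization, also with an estimated correlation, and the DNA replication list between RasV12 and L2 was placed lower by fry (median 0.086). Of the values of called lists, 359 stayed, 114 lost the call and these 3 turned. The cause was not tested except where stated.

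Leaving out single arrays gave 6230 to 7160 probe sets for RasV12 against CL8 (3703 to 3816 at least 2-fold apart), 7353 to 8750 for L2 against CL8 and 5689 to 8560 for RasV12 against L2, and 11 to 13, 6 to 7 and 5 to 6 lists. For L2 against CL8, 3997 probe sets were called among those with a mean above the median, 5245 after quantile normalization, 5059 with the floor and 5704 among probe sets above the background controls (chosen after seeing the data). For RasV12 against L2 the mean filter left 3649 and the floor 4802, and array weights, whose estimation stopped before it converged, gave 12740. Fewer probe sets tested lowers the filtered counts, and the floor removes differences within background, which limits what dim probe sets can show.

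Median centring called 7 lists for RasV12 against CL8 and 10 for L2 against CL8, and quantile normalization 6 and 2. An estimated correlation left 0 lists in each comparison in both scalings. Fry, which does not compare a list with other genes, called 27, 24 and 20. Without CL8 arrays 3 and 4, or 1 and 2 (both chosen after seeing the data), RasV12 against CL8 had 6731 and 7147 probe sets and 10 lists each. The glycolysis list lost its call without CL8 arrays 3 and 4 (adjusted p = 0.153), the mesoderm list without 1 and 2 (adjusted p = 0.0742), and the cytoplasmic ribosomal protein and glial lists in both cases. Without either pair the differences of Hsp27, Lac, Pxn, aos, boi and kek1 between RasV12 and CL8 moved by more than 1.5-fold and kept direction and call.

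Replicate numbers shared by RasV12 and CL8 were tried as a replicate block. It gave 6334 probe sets (3845 at least 2-fold apart) and 12 lists. Deviations of same-numbered arrays correlated at -0.245, -0.098 and -0.088, so the numbers do not pair the samples, and no array correlated best with its own number.

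Distances between arrays moved with the probe sets taken. For L2 and CL8, RasV12 and CL8, and RasV12 and L2 they were 0.421, 0.693 and 0.607 on the top 10%, 0.050, 0.0628 and 0.0625 on all probe sets, and 0.264, 0.392 and 0.382 with Spearman correlation. Quantile normalization gave 0.304 for L2 and CL8. Within CL8 all probe sets gave 0.00597, and within RasV12 the top 10% gave 0.0144 and all probe sets 0.00294. Leaving out single arrays gave 0.278 to 0.293, 0.413 to 0.425 and 0.398 to 0.414 between lines, and 0.0107 to 0.0143 within RasV12. L2 joined CL8 first in the main setting and the 4 settings tried on all arrays. These settings cannot separate a difference between the lines from a separate processing run of RasV12.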

Other observations

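All tests in this part except that of the xenobiotic list were chosen after the results were seen. Some genes of enzymes that modify foreign compounds are among those highest in RasV12 over CL8, but the list of oxidative stress and xenobiotic response genes fixed before the data were examined was not called (7 of 30 higher and 12 lower, median -0.27, camera adjusted p = 0.455, and 0.939 rescaled). GstE7, which like GstE6 was taken by the rule for named genes, was at least 46.2-fold higher, while GstE1 went the other way at -4.17 (-3.53 rescaled) and Cyp6w1 was at least 441-fold lower. Cyp6a13 was at least 129-fold higher, Cyp28d1 was higher by 6.49 (6.85 rescaled), Ugt302C1 by 5.53 (6.15 rescaled) and GstE8 by 3.67 (4.14 rescaled). These last 4 genes were chosen after their values were seen, and probes of close relatives can cross-hybridise.

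A hypothesis drawn from this is that these families may stand higher in RasV12 as wholes. It was tested on the members the text's rule for named genes had not taken, among 7628 genes above the background controls in RasV12 or CL8, of which 5.94% were at least 2-fold higher in both scalings. Of the remaining cytochrome P450 genes, 5 of 40 were so higher (Fisher's exact test, two-sided, adjusted p = 0.172), of the glutathione S-transferases 4 of 19 (adjusted p = 0.0699) and of the UDP-glycosyltransferases 4 of 16 (adjusted p = 0.0699). No family passed the threshold, although the 4 genes chosen after seeing their values are among those counted. With the named genes included the counts were 10 of 46, 6 of 23 and 4 of 17 (adjusted p = 0.00384, 0.00894 and 0.0438; for the UDP-glycosyltransferases the unadjusted p rose from 0.0126 to 0.0219), but the question came from those genes, and neighbouring genes of one family are not independent. The hypothesis stays open.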
